A study of Mus musculus with 24 samples.

How the data were processed

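RNA had been extracted with Trizol from livers frozen in liquid nitrogen, and libraries had been made with standard Illumina protocols, per the labels. The deposited table holds 55536 genes named by symbol and 24 libraries, in TPM as the authors deposited it, with 2 decimals. The unit was read from the values, since no header names it: columns summed to just under 1000000 in each library, and the smallest values above 0 fell with transcript length, as values divided by length do (median 0.17 TPM over 1999 genes of 300 to 600 bases, 0.02 TPM over 5687 genes of 3000 to 6000 bases). Only edgeR is named in the submitters' processing notes, with no version. The aligner, the genome build, the annotation and the step that made TPM are not given in the sources used here. Because TPM keeps no read counts, no counting interval could be given and count-based tests could not be run. Because values are relative to a fixed total, a rise of abundant transcripts lowers the values of all others.

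Of the gene names, 99.81% occur in the GENCODE M21 mouse annotation, which was used for transcript lengths, GC content, overlapping genes and shared sequence, and no coordinates are printed. Names were kept as deposited. Among the entries 237 share 117 symbols and were kept apart as separate entries, 27 carry names turned into dates, and 28559 are 0 in every library. All 24 libraries were mapped to groups and numbers by their titles, with 8 libraries in each of the 3 groups, and 0 columns stayed unmapped. The groups share no replicate numbers and the labels name no batch, day or litter.

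The main test, its lists of genes, the rule for named genes and the alternatives planned beforehand were fixed before the data were examined. The plan named count-based tests for read counts and, for normalized values, limma, which was therefore used. Values were taken as log2(TPM + 1), genes with a mean of at least 1 TPM over all libraries were kept (10555, with 44981 left out), and limma 3.58.1 in R 4.3.3 was fitted with an intensity trend to all 24 libraries by group (21 residual degrees of freedom). Genes passed at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. Members of a list are called measured where they were among the genes kept by the filter. Gene lists with at least 3 measured members (37 of 41, the 41 being 26 pathway and 15 marker lists) were tested against all other genes with camera, from limma, with a preset correlation between genes of 0.01 and again with a correlation estimated per list, adjusted over lists within a comparison. With the estimated correlation camera called 0 lists in each comparison (1, 2 and 2 lists had an unadjusted p under 0.05 for AP against controls, SAP against controls and SAP against AP), so every call of a list rests on the preset value. Counts of members that passed are given over all genes tested and adjusted over the list alone. The lists cover acute-phase proteins, cytokines and NF-kB feedback, interferon-stimulated genes, STAT3 signalling, immediate-early genes, metallothioneins and NRF2 targets, the unfolded protein response, heat-shock proteins, cytochromes P450, bile acids, cholesterol synthesis, fatty acid synthesis and oxidation, gluconeogenesis, urea cycle and amino acids, clock, cell cycle, p53 targets, coagulation and complement, extracellular matrix, growth hormone axis, female-biased genes, glucocorticoid response, respiratory chain, ribosomal proteins and proteasome. The marker lists cover neutrophils, monocytes, Kupffer cells, T and NK cells, B cells, endothelium, stellate cells, cholangiocytes, red cells, platelets, exocrine pancreas, adipocytes, and secreted, pericentral and periportal hepatocyte genes.

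Named genes were, per comparison, the 5 with the largest rise and the 5 with the largest fall among genes that passed with a mean of at least 5 TPM, leaving out predicted and clone-named genes and receptor segments, and from each list the members with the smallest p of the test over all groups, 3 per pathway list and 2 per marker list. Some genes are not reported here, and were left out of the test for single libraries far from their group, but stayed in all other tests and counts. Transcripts of named genes were compared with all other transcripts in windows of 50 bases, and a level was taken as uncertain from 20% of shared windows or where genes overlap. Measures of single libraries (totals, shares of TPM) and list scores per liver were compared by exact permutation tests, two-sided, over all 12870 arrangements of 8 against 8 libraries, adjusted over 24 tests of library measures or 37 lists. A list score is the mean log2 value of the members minus the median of all tested genes.

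The alternatives planned beforehand were quantile normalization, centring of each library on its median, limma without trend or with array weights, no filter or a stricter one (1 TPM in at least 8 libraries), pseudocounts of 0.1 and 0.01, the 2 groups alone, other thresholds, and leaving out each library. Added after the data were seen were rescaling without the 50 most abundant genes, leaving out Con 3 and 9, SAP 21 to 25 or SAP 26 to 29, a covariate for the lower or upper numbers in the titles, removal of trends on transcript length and GC content (known for 99.73% of tested genes), and list scores. Comparisons with shared controls were set beside 100 simulations of unchanged groups, lists of the same sizes drawn independently, and 70 splits of the controls into sets of 4.

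The tests were tried on simulated data of the same size, in which genes varied independently, with 50 genes per fold size. Changes of 0.5, 1, 2 and 3 on the log2 scale were recovered in 24, 80, 96 and 98% of genes for AP against controls (6 false calls among 10355 unchanged genes), in 40, 90, 100 and 98% for SAP against controls (13 false calls) and in 34, 80, 98 and 100% for SAP against AP (9 false calls). In each comparison 5 of 5 shifted lists were called, with 1, 1 and 0 unshifted lists called. Because simulated genes were independent, these counts do not give the false calls of camera in the real data. There, other splits of the libraries called a median of 10, 13 and 13 lists. Those splits mix livers of the groups compared, so these medians are not counts of false calls between unchanged groups either. Tables and figures were made with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, Matplotlib 3.10.9 and the R package data.table (version 1.17.8).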

Results

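RNA was sequenced in 24 liver libraries from wild-type Balb/c mice aged 6 weeks. Of these, 8 came from healthy controls (Con), 8 from acute pancreatitis (AP), an inflammation of the pancreas, and 8 from severe acute pancreatitis (SAP), the form in which organs outside the pancreas can fail. How pancreatitis was induced, and when the livers were taken, are not given in the sources used here. The labels number the libraries of a group as 8 repeats without stating that each came from a different mouse, so p-values measure the spread between these libraries, and a liver stands for a library in the text. Expression was given in transcripts per 1000000 (TPM). Libraries summed to between 986423 and 993642 TPM, and TPM keeps no record of sequencing depth, so the depth is unknown. Between 17140 and 18565 genes per library were listed above 0 TPM, and the 10555 genes with a mean of at least 1 TPM were tested. Levels are given as mean ± SD over the 8 livers of a group. Fold changes are on the log2(TPM + 1) scale, which understates the change of genes with low levels, and log2 changes carry their standard error. Adjusted p-values of single genes come from limma.

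The first principal component of the log2 values held 61.0% of the variance and separated the 8 SAP livers from all AP and control livers, and the second held 7.48%. Across genes, which are not independent replicates, libraries correlated with r between 0.941 and 0.966 within controls, 0.940 and 0.973 within AP, and 0.925 and 0.974 within SAP. AP and control libraries correlated with r between 0.915 and 0.967, and SAP and control libraries between 0.711 and 0.836. Transcripts of the mitochondrial genome made up 17.1 ± 3.68% of TPM in controls, 10.9 ± 1.996% in AP and 4.46 ± 1.02% in SAP. Their share was lower in AP than in controls (exact permutation test, two-sided, p = 0.000622, adjusted p = 0.00213 over 24 tests of library measures). It was lower in all 8 SAP livers than in any control (exact permutation p = 0.000155, the smallest these groups can give, adjusted p = 0.000932). Serum amyloid A genes, which encode acute-phase proteins, made up 0.327 ± 0.411% in controls, 0.731 ± 0.366% in AP (exact permutation adjusted p = 0.109) and 9.52 ± 1.98% in SAP (exact permutation adjusted p = 0.000932). Within SAP, libraries 21, 22, 24 and 25 stood apart from libraries 26 to 29. A limma test between these sets of 4, a division by the numbers in the titles that was chosen after the data were seen, called 3708 genes, 3170 higher and 538 lower in 26 to 29.

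**Figure D1:**
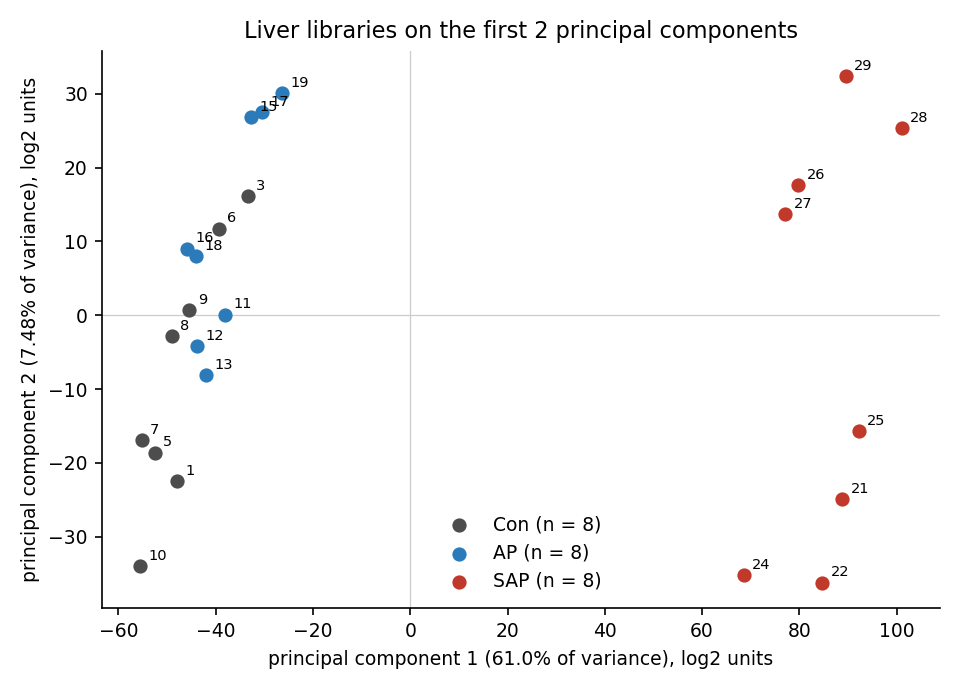
Principal components of log2(TPM + 1) values of the 24 liver libraries. The horizontal axis is the first component (61.0% of the variance) and the vertical axis the second (7.48%), each point is 1 library labelled with its number, and colours mark control, AP and SAP livers, with SAP apart on the first component.

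The comparison of AP with control livers asked which hepatic transcripts differ in mice with acute pancreatitis. Of 25 measured genes of fatty acid oxidation and PPAR-alpha targets 12 rose in AP livers, and 6 of 20 genes of fatty acid and triglyceride synthesis fell. Cyp4a14, a fatty acid omega-hydroxylase and target of the nuclear receptor PPAR-alpha, rose from 9.78 ± 7.19 TPM in controls to 80.2 ± 32.5 TPM in AP (n = 8 each), an 8.65-fold rise with all 8 AP livers above every control (limma adjusted p = 0.00015). Plin2, a coat protein of lipid droplets, rose 1.76-fold from 62.2 ± 11.8 to 111 ± 22.3 TPM (adjusted p = 0.00668), with 7 of 8 AP livers above every control. Elovl6, a fatty acid elongase, fell from 13.7 ± 4.42 to 5.85 ± 2.33 TPM (adjusted p = 0.00262).

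Of the 10555 genes tested, 578 passed the test between AP and control livers, 459 higher and 119 lower in AP, which is 5.48% of genes and 79.4% of changes upward. Of these, 84 differed by at least 1 on the log2 scale (53 up, 31 down). The split between rises and falls depended on scaling. It was 388 up and 265 down after quantile normalization, and 194 up and 215 down after rescaling without the 50 most abundant genes, where the median log2 change of the genes tested was 0.01 and -0.06, against 0.06. Rescaling also raised the number of genes tested to 12559. It moved the 10505 genes tested both ways nearly alike, by a median log2 of -0.12 (quartiles -0.14 and -0.10). The 50 most abundant genes held 57.1 ± 2.88% of TPM in controls and 52.97 ± 1.53% in AP (exact permutation adjusted p = 0.00915). The count fell to 210, 180, 226, 181, 211, 340 or 237 genes without Con 1, Con 7, Con 10, AP 15, AP 17, AP 18 or AP 19 respectively. These controls had the highest mitochondrial shares of TPM (19.84 to 22.19%, other controls 12.51 to 16.03%). These AP livers had the lowest (7.81 to 10.28%, other AP livers 11.46 to 13.71%). Whether that share bears on the number of calls was not tested.

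The largest rises among genes with a mean of at least 5 TPM were those of Cyp4b1-ps1 (a pseudogene, 12.0-fold to 69.2 ± 41.9 TPM), Cyp4a14, Derl3, Saa2 and RPS10-NUDT3. Derl3, which takes part in degradation of proteins of the endoplasmic reticulum, rose 6.49-fold from 3.80 ± 1.75 to 29.2 ± 8.11 TPM, in all 8 livers above every control (adjusted p = 0.000409). Saa2, a serum amyloid A gene, rose 5.22-fold by the means of log2 values (limma adjusted p = 0.0238), with mean levels of 1414 ± 2059 and 3295 ± 1913 TPM. Only 2 of 8 AP livers lay above every control, and the control mean was 831.5 TPM without Con 3. The largest falls were those of Cyp2c69, Nop9, Fyb, Rpl17-ps3 and Scd1. Scd1, which desaturates fatty acids, went from 31.5 ± 13.6 to 10.6 ± 9.36 TPM (adjusted p = 0.0348), and Cyp2c69, a cytochrome P450, from 52.4 ± 32.2 to 9.30 ± 9.61 TPM (adjusted p = 0.00151). Several of these levels are uncertain because the 50-base windows of the transcripts also occur in other genes, 35.0% of windows for Cyp4b1-ps1, 31.8% for Saa2, 94.5% for RPS10-NUDT3, 54.8% for Cyp2c69 and 81.5% for Rpl17-ps3. Fyb and RPS10-NUDT3 overlap other genes on their own strand, and Nop9 overlaps Cideb on the opposite strand. AP livers were not alike for several of these genes. Nop9 was between 5.88 and 27.42 TPM in AP 15, 17, 18 and 19 and between 76.52 and 111.03 TPM in AP 11, 12, 13 and 16. Fyb was between 0.68 and 18.61 TPM in the former and 30.7 and 57.23 in the latter, and Rpl17-ps3 between 3.24 and 8.01 and between 18.09 and 57.67 TPM. Among all 35 splits of the 8 AP livers into sets of 4, this split, found from the values, called the most genes (688), and the labels name nothing that separates these livers. The sets also differed in the mitochondrial share of TPM, which was 7.81 to 10.28% in AP 15, 17, 18 and 19 and 11.46 to 13.71% in AP 11, 12, 13 and 16.

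Of the 37 gene lists tested, 13 passed between AP and controls, 9 upward and 4 downward, and 0 with a correlation between genes estimated per list. In the list of fatty acid oxidation and PPAR-alpha targets 12 of 25 genes rose, 13 did not pass and none fell (19 rose adjusted over the list alone). The list passed (camera adjusted p = 1.67e-15, adjusted p = 0.183 with an estimated correlation). Its mean log2 level per liver, taken relative to the median of all genes, was 3.08 ± 0.19 in AP and 2.33 ± 0.25 in controls, with all 8 AP livers above every control (exact permutation adjusted p = 0.00575 over 37 lists). This score per liver was added after the data were seen. Pdk4, which restrains glucose oxidation, was at 0.375 ± 0.201 and 0.347 ± 0.0990 TPM and did not pass. Of 20 genes of fatty acid and triglyceride synthesis, 6 fell, 1 rose and 13 did not pass (7 fell and 3 rose adjusted over the list alone, camera adjusted p = 0.000264, adjusted p = 0.683 with an estimated correlation, exact permutation adjusted p = 0.0827 for the score per liver). Acss2, which makes acetyl-CoA from acetate, fell from 13.97 ± 3.05 to 9.99 ± 2.17 TPM (adjusted p = 0.0403), and the gene that rose was Dgat2, which completes triglyceride synthesis. Where 5 or fewer members of a list passed, those named were chosen after their values were seen.

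Among 13 cytosolic heat-shock genes, Hspa1b, Hspa8 and Hspe1 rose and 10 did not pass (10 rose adjusted over the list alone, camera adjusted p = 3.26e-05, adjusted p = 0.683 with an estimated correlation, exact permutation adjusted p = 0.0103 for the score per liver). Hspa1b, an inducible chaperone that shares 62.3% of its windows chiefly with Hspa1a and is therefore uncertain, rose 2.09-fold to 13.6 ± 3.95 TPM (adjusted p = 0.0119). Of 22 genes of the unfolded protein response, Atf5, a transcription factor, rose from 164 ± 40.1 to 294 ± 38.7 TPM and 21 did not pass (6 rose adjusted over the list alone, camera adjusted p = 0.000264, adjusted p = 0.731 with an estimated correlation, exact permutation adjusted p = 0.00863). The chaperone Hspa5 was at 55.1 ± 19.0 TPM in controls and 94.9 ± 42.8 in AP (adjusted p = 0.0835) and Xbp1 at 19.8 ± 7.89 and 32.4 ± 15.5 TPM (adjusted p = 0.0822). Both passed without Con 3 (adjusted p = 0.0437 and 0.0274), and Hspa5 also without AP 13 (adjusted p = 0.0465).

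Of 29 acute-phase genes, 6 rose in AP and 23 did not pass (11 rose adjusted over the list alone, camera adjusted p = 0.00499, adjusted p = 0.731 with an estimated correlation, exact permutation adjusted p = 0.227), and rescaling without the 50 most abundant genes ended the call (adjusted p = 0.0695). Fgg, a fibrinogen chain, rose 1.66-fold from 399 ± 131 to 657 ± 235 TPM (adjusted p = 0.0409), and Cd14, a receptor for bacterial lipopolysaccharide, was at 2.71 ± 5.04 and 1.45 ± 0.483 TPM, with a control mean of 0.927 TPM without Con 3. Serum amyloid A genes took 1.14% of TPM in Con 3 and 0.8% in Con 9, against 0.051 to 0.219% in the other controls. In limma, none of 23 cytokine, chemokine and NF-kB feedback genes passed, and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.0581), although the list passed as lower with the 2 groups alone (adjusted p = 0.0328), with length and GC trends removed (0.0248), with the covariate for title numbers (0.00187) and without SAP 21 to 25 or 26 to 29 (0.0385 and 0.0343). The interferon-stimulated genes fell as a list (camera adjusted p = 0.00499, adjusted p = 0.731 with an estimated correlation, exact permutation adjusted p = 0.583), with 1 of 26 members passing and 0 adjusted over the list alone. That gene was Oas2, an antiviral enzyme, at 2.68 ± 1.11 and 1.23 ± 0.634 TPM, and rescaling without the 50 most abundant genes ended the list's call (adjusted p = 0.0719).

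Genes of 3 large complexes passed in a part of their members. In the nuclear-encoded respiratory chain 25 of 82 genes rose and 57 did not pass (40 rose and 2 fell adjusted over the list alone, camera adjusted p = 2.85e-09, adjusted p = 0.683 with an estimated correlation, exact permutation adjusted p = 0.123), and quantile normalization ended the call (adjusted p = 0.0953). Ndufs8, a complex I subunit, was at 227 ± 15.0 and 222 ± 20.9 TPM and did not pass. Of 76 cytosolic ribosomal protein genes, 20 rose and 56 did not pass (39 rose and 2 fell adjusted over the list alone, camera adjusted p = 3.15e-10, adjusted p = 0.731 with an estimated correlation, exact permutation adjusted p = 0.0805). Rps15 was at 1270.4 ± 123 and 1455 ± 91.7 TPM and did not pass. Of 37 proteasome genes, 7 rose and 30 did not pass (21 rose adjusted over the list alone, camera adjusted p = 1.66e-07, adjusted p = 0.731 with an estimated correlation, exact permutation adjusted p = 0.0115). Psmd13, a proteasome subunit, rose 2.09-fold from 4.29 ± 2.01 to 10.4 ± 5.23 TPM (adjusted p = 0.0204). It was between 11.54 and 18.74 TPM in AP 15, 17, 18 and 19, while AP 11, 12, 13 and 16 (5.53 to 6.37 TPM) lay within the range of controls (2.01 to 7.36 TPM).

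A further 4 lists passed. Among 31 coagulation and complement genes, F2, Proc and Mbl1 rose and C9 fell (10 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.00946, adjusted p = 0.731 with an estimated correlation, exact permutation adjusted p = 0.00767), and quantile normalization ended the call (adjusted p = 0.697). Among 9 pericentral hepatocyte genes, Cyp2e1 (from 1374 ± 358 to 3055 ± 744 TPM) and Slc1a2 rose (5 adjusted over the list alone, camera adjusted p = 0.00175, adjusted p = 0.683 with an estimated correlation, exact permutation adjusted p = 0.00575). Among 7 stellate cell markers Ecm1 fell (1 adjusted over the list alone, camera adjusted p = 0.0119, adjusted p = 0.683 with an estimated correlation, exact permutation adjusted p = 0.155). Of 24 genes of cholesterol synthesis none passed in limma, 0 adjusted over the list alone and 1 at an unadjusted p under 0.05, although the list fell (camera adjusted p = 0.0288, adjusted p = 0.731 with an estimated correlation, exact permutation adjusted p = 0.277), and that call ended after rescaling without the 50 most abundant genes (adjusted p = 0.0719), with no filter (0.135) and with the covariate for title numbers (0.0621).

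The other lists did not pass between AP and controls in the main test. With no filter, the growth hormone (adjusted p = 0.00336), cytochrome P450 (0.0179) and hepatocyte secreted (0.0203) lists passed as higher and the cell cycle list (0.0203) as lower. Passing as lower were also the urea cycle list after quantile normalization (0.0332) and without Con 3 and 9 (0.0336), the NRF2 list after quantile normalization (0.0402), with the covariate for title numbers (0.0356) and with length and GC trends removed (0.0335), and the immediate-early list with that covariate (0.0373). Among their members, 3 of 25 cytochrome P450 genes rose (Cyp2d26, Cyp2e1, Por), as did 2 of 25 bile acid genes (Cyp7b1, Slc10a1), 2 of 18 gluconeogenesis genes (Fbp1, Pcx), 1 of 24 urea cycle and amino acid genes (Slc25a13), 1 of 13 growth hormone axis genes (Egfr), 1 of 7 female-biased genes (Acot3) and 1 of 13 hepatocyte secreted proteins (Rbp4). Adjusted over the list alone, these counts were 3, 5, 2, 2, 1, 3 and 4 rises, with 1 fall each among bile acid and hepatocyte secreted genes. Gstm1 and Gstm3, glutathione transferases, fell among 17 metallothionein and NRF2 target genes (2 fell and 1 rose adjusted over the list alone). Gstm3 went from 24.0 ± 8.32 to 6.69 ± 2.93 TPM, in all 8 AP livers below every control (adjusted p = 8.19e-05), and is uncertain because 28.8% of its windows occur in other genes. No gene passed in limma, over all genes or adjusted over the list alone, in the lists of STAT3 signalling, immediate-early genes, clock, cell cycle, p53 targets, extracellular matrix, glucocorticoid response and periportal genes. The same held for markers of neutrophils, monocytes, Kupffer cells, sinusoidal endothelium, cholangiocytes, red cells and adipocytes, and each of these lists had at most 2 members at an unadjusted p under 0.05. Median, mean and test differed in sign for the NRF2 (median 0.05, mean -0.11), STAT3, cell cycle, extracellular matrix and endothelial lists.

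Of the 122 genes that the naming rule gave, 19 passed between AP and controls, and in 4 of these (Cyp4b1-ps1, Cyp4a14, Derl3, Gstm3) the groups did not overlap. Among all 10555 genes tested 79 did not overlap, and chance gives this with a probability of 0.000155 for a single gene chosen in advance. Several of these calls ended without single libraries. Saa2 missed without Con 1, Con 10, AP 15 or AP 19 (adjusted p = 0.0573 to 0.0618), and Psmd13 without Con 1, 7 or 10 or AP 15 (0.0508 to 0.0571). Fyb missed without Con 1, 7 or 10 or AP 15, 17 or 19 (0.0551 to 0.0638), and Rpl17-ps3 without these or AP 18 (0.0506 to 0.0638). RPS10-NUDT3 missed without Con 1, 7 or 10 or AP 11, 15, 16, 17 or 19 (0.0504 to 0.0893), and Scd1 without Con 1, 5, 7, 9 or 10 or AP 16, 17 or 18 (0.0544 to 0.072). Fgg missed without Con 1, 5, 7, 8 or 10 or AP 11, 15, 17 or 19 (0.0566 to 0.108). Acss2 missed without Con 1, 5, 6, 7, 9 or 10 or AP 11, 13, 15, 16, 17 or 18 (0.0538 to 0.0805).

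The comparison of SAP with control livers asked which hepatic transcripts differ in the severe disease. In SAP livers 27 of 29 acute-phase genes and 23 of 23 cytokine, chemokine and NF-kB feedback genes rose, while 16 of 25 bile acid genes and 16 of 25 cytochrome P450 genes fell and 6 and 4 rose. These lists passed camera with its preset correlation and not with an estimated one. Cd14 rose from 2.71 ± 5.04 to 817 ± 247 TPM, a 316-fold rise (limma adjusted p = 8.2e-17). Saa3, an acute-phase gene, rose from 192 ± 346 to 21325 ± 6856 TPM (adjusted p = 3.81e-11), and Il1rn, the interleukin-1 receptor antagonist, from 0.969 ± 1.47 to 163 ± 50.7 TPM (adjusted p = 2.57e-17). Con 3 was the highest control for these genes, and the control means without it were 0.927 TPM for Cd14, 71.5 for Saa3 and 0.459 for Il1rn. Abcb11, the bile salt export pump, fell from 159 ± 25.4 to 4.48 ± 2.03 TPM (adjusted p = 1.21e-17).

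Between SAP and control livers 7808 of 10555 genes passed (74.0%), 4661 higher and 3147 lower in SAP, and 4031 of them differed by at least 1 on the log2 scale (2395 up, 1636 down). The median log2 change of all genes was 0.21. With each library centred on its median the split was 3888 up and 4300 down, with a median of -0.06. Centring moves all genes of a library alike, so the balance of rises over falls depended on where the middle of the genes was set. Of the 122 named genes 119 passed, 105 of them with no overlap between groups, and Scd1, Mcm3 and Ighm did not. The named genes were chosen by their values, and among all 10555 genes tested 3995 did not overlap. Other large rises were those of Igfbp1, which binds insulin-like growth factors (1.74 ± 1.03 to 908 ± 730.5 TPM), and Saa2 (41564 ± 7032 TPM in SAP). Ccdc152, which lies opposite the selenoprotein P gene and is uncertain for that reason, fell from 563 ± 118 to 4.46 ± 2.30 TPM. Apol11b, an apolipoprotein L gene, fell from 598 ± 140.2 to 12.9 ± 15.3 TPM (8.37 TPM in SAP without SAP 24). Angptl8, a secreted regulator of triglyceride clearance, fell from 213 ± 95.2 to 2.61 ± 1.41 TPM (adjusted p = 1.15e-15). The ribosomal RNA genes n-R5s128 and n-R5s146, whose windows all occur in other genes, were listed at 0 in all 8 SAP livers and above 0 in 6 and 7 control livers.

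Of the 37 lists, 15 passed between SAP and controls, 9 upward and 6 downward, and 0 with an estimated correlation. Of 29 acute-phase genes, 27 rose in SAP and 2 did not pass (camera adjusted p = 1.53e-07, adjusted p = 0.668 with an estimated correlation). The count was also 27 adjusted over the list alone, and these counts were equal for every list in this comparison unless both are given. The score of the list per liver was 8.31 ± 0.10 in SAP and 5.22 ± 0.59 in controls, with all 8 SAP livers above every control (exact permutation adjusted p = 0.000359). Fgg rose 33.0-fold to 12929 ± 3371 TPM (adjusted p = 1.93e-16). All 23 measured genes of cytokines, chemokines and NF-kB feedback rose (camera adjusted p = 1.13e-05, adjusted p = 0.668 with an estimated correlation, exact permutation adjusted p = 0.000359), among them Ccl5, a chemokine (from 6.06 ± 9.38 to 167 ± 69.7 TPM, the control mean being 2.76 without Con 3), Selp, an adhesion molecule (0.657 ± 0.219 to 21.5 ± 7.40 TPM), and Irak3, an inhibitor of Toll-like receptor signalling (0.122 ± 0.0939 to 15.3 ± 4.18 TPM). Within SAP, 12 of these 23 genes were lower and 1 higher in libraries 26 to 29 than in 21 to 25. Neutrophil markers rose in 6 of 6 genes (camera adjusted p = 0.00119, adjusted p = 0.668 with an estimated correlation, exact permutation adjusted p = 0.000359). The filter on mean TPM kept 6 of 14 neutrophil markers, 23 of 26 cytokine genes and 14 of 18 immediate-early genes. Genes near 0 in controls and AP could pass it only through SAP, so such counts of rises are partly fixed by the filter. Ngp, a neutrophil granule protein, was at 0.0362 ± 0.0646 TPM in controls and 6.39 ± 2.90 in SAP, and Il1r2, a decoy receptor for interleukin-1, at 0.0400 ± 0.0521 and 3.92 ± 1.25 TPM, with control means of 0.0157 TPM for Ngp without Con 9 and 0.0257 TPM for Il1r2 without Con 6.

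Of 14 genes of STAT3 and cytokine-receptor signalling, 12 rose and 2 did not pass (camera adjusted p = 0.00119, adjusted p = 0.668 with an estimated correlation). Socs3, a feedback inhibitor of cytokine receptors, rose from 4.36 ± 1.69 to 55.1 ± 13.7 TPM, Cebpd, a transcription factor of the acute-phase response, from 1.69 ± 1.48 to 22.5 ± 6.42 TPM, and Osmr, the oncostatin M receptor, by 1.52 ± 0.11 on the log2 scale. All 14 immediate-early genes rose (camera adjusted p = 0.000145, adjusted p = 0.668 with an estimated correlation), including Ier3, a stress-induced survival gene (0.929 ± 0.603 to 131 ± 30.1 TPM), Egr1, a zinc-finger transcription factor (0.427 ± 0.398 to 25.2 ± 8.73 TPM), and Klf6. Of 14 p53 targets and apoptosis genes, 13 rose and Bbc3, a promoter of apoptosis, fell (camera adjusted p = 0.0143, adjusted p = 0.696 with an estimated correlation). Cdkn1a, the cell cycle inhibitor p21, rose from 1.96 ± 2.19 to 100.4 ± 38.9 TPM (control mean 1.22 without Con 3), Aen from 3.22 ± 1.67 to 24.6 ± 4.85 TPM, and Sesn2 also passed. For all 3 lists the exact permutation adjusted p of the score per liver was 0.000359.

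Of 22 genes of the unfolded protein response, 20 rose, 1 fell and 1 did not pass (camera adjusted p = 1.93e-05, adjusted p = 0.668 with an estimated correlation, exact permutation adjusted p = 0.000359). Hspa5, the main chaperone of the endoplasmic reticulum, rose from 55.1 ± 19.0 to 1595 ± 590.0 TPM (adjusted p = 1.37e-14), Xbp1, a transcription factor of this response, from 19.8 ± 7.89 to 285 ± 40.4 TPM, and Chac1, which degrades glutathione, from 0.679 ± 0.306 to 27.6 ± 11.8 TPM. The gene that fell was Atf5 (164 ± 40.1 to 81.2 ± 20.4 TPM). Of 37 proteasome genes, 26 rose and Psmd4, Psmb6, Psma3, Psmb3 and Psmb9 fell (camera adjusted p = 0.016, adjusted p = 0.728 with an estimated correlation, exact permutation adjusted p = 0.000359), with Psmd8 going from 36.6 ± 9.32 to 178 ± 39.8 TPM and Psmd10 from 1.74 ± 0.538 to 12.8 ± 2.62 TPM, and within SAP 13 proteasome genes were higher and 3 lower in libraries 26 to 29.

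**Figure D2:**
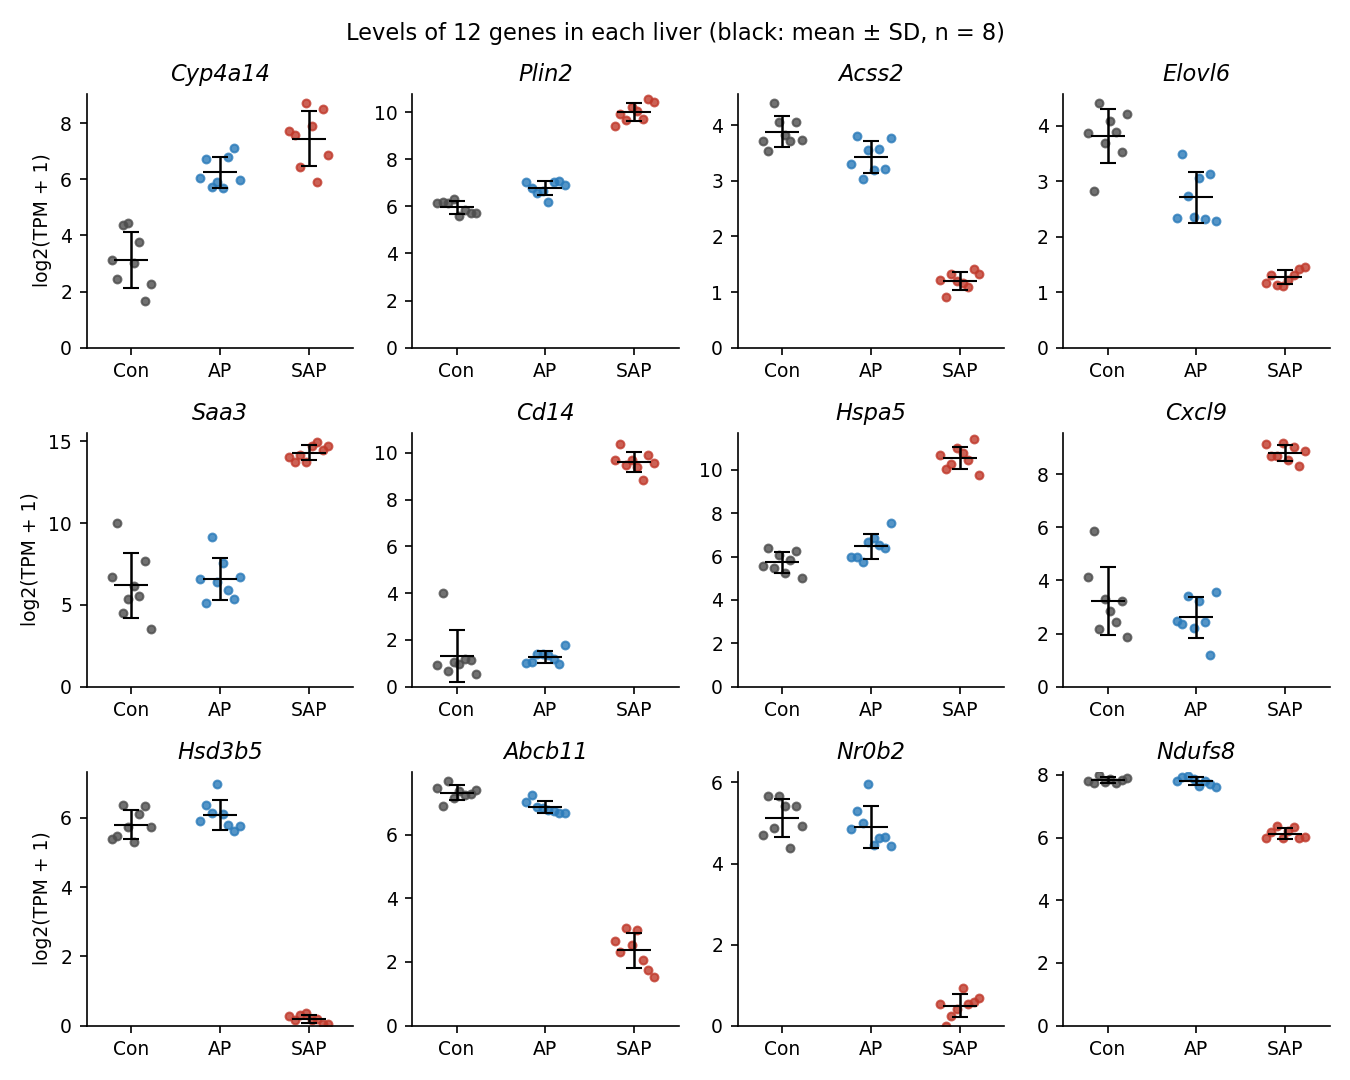
Levels of 12 named genes in single livers, as log2(TPM + 1) on the vertical axis, for control, AP and SAP groups on the horizontal axis. Points are livers, and bars show the mean ± SD of the log2 values (n = 8 per group). Before the log2 step, Cd14 was at 2.71 ± 5.04 TPM in controls and 817 ± 247 TPM in SAP.

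Lipid genes moved in both directions in SAP. Of 25 genes of fatty acid oxidation and PPAR-alpha targets, 21 rose and 3 fell, Cpt2 and Ech1 among them (camera adjusted p = 0.00194, adjusted p = 0.728 with an estimated correlation, exact permutation adjusted p = 0.000359). Plin2 rose from 62.2 ± 11.8 to 1056 ± 284 TPM (adjusted p = 8.51e-17) and Pdk4 from 0.375 ± 0.201 to 35.5 ± 22.0 TPM. Of 20 genes of fatty acid and triglyceride synthesis, 12 fell and Fasn, Me1 and Lpin1 rose (camera adjusted p = 0.016, adjusted p = 0.728 with an estimated correlation, exact permutation adjusted p = 0.000359). Elovl6 fell from 13.7 ± 4.42 to 1.41 ± 0.216 TPM and Acss2 to 1.31 ± 0.247 TPM. The call of the synthesis list ended without SAP libraries 26 to 29 (adjusted p = 0.0606). Of 24 genes of cholesterol synthesis, 16 fell and Srebf2 and Hsd17b7 rose (camera adjusted p = 0.00206, adjusted p = 0.728 with an estimated correlation, exact permutation adjusted p = 0.000359). Mvk, mevalonate kinase, fell from 11.9 ± 1.47 to 2.16 ± 1.72 TPM, Fdft1, squalene synthase, from 42.8 ± 9.38 to 17.6 ± 7.17 TPM, and Acat2 also passed. Within SAP, 20 of the 24 cholesterol genes were higher in libraries 26 to 29 and none lower.

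Of 25 genes of bile acid synthesis and transport, 16 fell and 6 rose (camera adjusted p = 0.00119, adjusted p = 0.668 with an estimated correlation, exact permutation adjusted p = 0.000359). Nr0b2, the bile acid-induced repressor SHP, fell from 35.6 ± 11.5 to 0.427 ± 0.273 TPM, and Slco1b2, an uptake transporter, from 37.4 ± 5.67 to 5.67 ± 2.12 TPM. Of 25 drug-metabolising cytochromes P450 and their receptors, 16 fell and Cyp2b10, Cyp2e1, Cyp3a11 and Cyp3a13 rose (camera adjusted p = 0.00206, adjusted p = 0.728 with an estimated correlation, exact permutation adjusted p = 0.000359). Nr1i3, the xenobiotic receptor CAR, fell from 53.9 ± 17.7 to 3.92 ± 1.11 TPM, Cyp2c40 from 372 ± 50.3 to 52.5 ± 29.7 TPM and Cyp2d22 from 117 ± 25.2 to 22.4 ± 7.12 TPM. Within SAP, 14 of the 25 were lower and 1 higher in libraries 26 to 29, and the call ended without those libraries (adjusted p = 0.0721). Of 17 metallothionein and NRF2 target genes, 10 fell and 4 rose, the metallothioneins Mt1 and Mt2, which bind metals, the heme oxygenase Hmox1, and Txnrd1 (camera adjusted p = 0.0418, adjusted p = 0.728 with an estimated correlation, exact permutation adjusted p = 0.000359), with Osgin1, an oxidative stress response gene, going from 134 ± 39.0 to 16.6 ± 9.12 TPM and Gclm, a subunit of the glutathione synthesis enzyme, from 69.7 ± 12.5 to 22.4 ± 3.21 TPM. That call ended after quantile normalization (adjusted p = 0.0929), with no filter (0.0519), without Con 3 and 9 (0.0616) and without SAP 26 to 29 (0.153).

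In the nuclear-encoded respiratory chain 39 of 82 genes fell, 25 rose and 18 did not pass (camera adjusted p = 0.0109, adjusted p = 0.728 with an estimated correlation, exact permutation adjusted p = 0.00253), while the mitochondrial genome's own share of TPM was also lower. Ndufs8 fell from 227 ± 15.0 to 69.4 ± 8.14 TPM (adjusted p = 4.89e-15) and Ndufv3, of the same complex, from 499 ± 35.5 to 138 ± 31.2 TPM. The list's call ended after quantile normalization (adjusted p = 0.234), with length and GC trends removed (0.138) and without SAP 26 to 29 (0.114).

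Several lists that did not pass held large single changes in both directions. Of 26 interferon-stimulated genes, 5 rose and 10 fell (5 and 8 adjusted over the list alone). Cxcl9, an interferon-induced chemokine, rose from 13.5 ± 18.3 to 453 ± 94.1 TPM (control mean 7.22 without Con 3), Gbp2, a guanylate-binding protein, from 2.24 ± 2.31 to 57.5 ± 24.8 TPM, and Gbp3, Gbp5 and Rsad2 also rose. Within SAP, 18 of the 26 were lower in libraries 26 to 29 and none higher, and without libraries 21 to 25 the list passed as lower than in controls (adjusted p = 0.016). Of 18 gluconeogenesis and glycogen genes, 6 rose and 8 fell, with a median log2 change of -0.61, a mean of 0.43 and a negative test. Tat, which degrades tyrosine, rose from 172 ± 42.9 to 1554 ± 379.8 TPM, and the glucose transporter Slc2a2 fell from 56.1 ± 16.1 to 3.91 ± 2.49 TPM. Of 31 coagulation and complement genes, 11 rose and 12 fell (median 0.01, mean -0.14). Klkb1, prekallikrein, fell from 34.4 ± 6.22 to 1.81 ± 0.919 TPM, as did Serpind1, heparin cofactor II (104 ± 16.6 to 11.2 ± 4.80 TPM). Within SAP 10 of the 31 were lower and 1 higher in libraries 26 to 29.

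In the growth hormone axis and male-biased list 7 of 13 genes fell and Egfr rose, and the list missed (camera adjusted p = 0.0533). It passed as lower with no filter (adjusted p = 0.0234), without SAP 21 to 25 (0.00228), with the covariate for title numbers (0.0322) and by the score per liver (difference -1.17, exact permutation adjusted p = 0.00131). Igf1, the main growth factor induced by growth hormone, fell from 1050.1 ± 195 to 472 ± 90.0 TPM (adjusted p = 6.7e-09), its carrier gene Igfals from 46.4 ± 10.2 to 6.88 ± 4.54 TPM, and Hsd3b5, a male-biased steroid enzyme, from 57.2 ± 17.5 to 0.142 ± 0.0915 TPM. Of 24 urea cycle and amino acid genes, 7 rose (Sdsl from 7.92 ± 2.25 to 90.3 ± 27.2 TPM) and 12 fell (Slc25a13 and Cbs among them), and 13 were lower and 3 higher in libraries 26 to 29. Of 15 clock genes, 8 rose (Per1, from 1.55 ± 0.635 to 18.3 ± 7.32 TPM) and 4 fell (among them Dbp, from 95.0 ± 33.4 to 6.17 ± 2.15 TPM, Per3 and Tef). The hour at which livers were taken is not given in the sources used here. Of 10 glucocorticoid-responsive genes, 7 rose (Gadd45g, from 25.0 ± 16.3 to 322 ± 55.6 TPM, and Errfi1) and Tsc22d3, Lpin2 and Pdk2 fell. Of 13 heat-shock genes, Hspd1 and Bag3 rose and 6 fell, Hspa1b and Chordc1 among them. Of 7 female-biased genes, Acot3 and Cyp17a1 rose and Cyp2b9, Cyp2b13 and Fmo2 fell. Of 6 cell cycle genes Ccne1 and Pcna rose. Of 13 extracellular matrix genes, 5 rose, namely Timp1 (1.17 ± 1.77 to 33.9 ± 10.2 TPM, control mean 0.566 without Con 3), Col4a1, Col4a2, Mmp2 and Mmp14, and Col1a1 and Col3a1 fell (1 adjusted over the list alone). Of 76 ribosomal protein genes, 24 rose and 22 fell, with a positive median and mean, a negative test, and 61 higher in libraries 26 to 29.

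Markers of other liver cell types did not move together. Of 11 Kupffer cell and macrophage markers, 8 fell and 1 rose, the scavenger receptor Marco (from 3.38 ± 7.64 to 15.9 ± 9.21 TPM, control mean 0.689 without Con 3), while Cd5l fell from 19.0 ± 12.8 to 3.99 ± 1.95 TPM (camera adjusted p = 0.117, exact permutation adjusted p = 0.0121). Of 10 sinusoidal endothelial markers, 6 fell (Dnase1l3, 28.1 ± 7.09 to 6.28 ± 1.29 TPM) and Stab2 and Lyve1 rose (Lyve1, 0.301 ± 0.158 to 11.2 ± 5.13 TPM), and 7 were higher in libraries 26 to 29. Of 7 stellate cell markers, Reln, Rgs5 and Dcn rose (Dcn from 23.1 ± 6.14 to 80.3 ± 20.5 TPM) and 4 fell, Des, Ecm1 and Colec11 among them (Colec11 from 11.6 ± 2.37 to 2.27 ± 0.778 TPM). Of 5 monocyte markers F13a1 and Fcgr1 fell, 0 adjusted over the list alone. F13a1 missed without Con 1, 3, 5, 7 or 10 or SAP 24, 25, 28 or 29 (adjusted p = 0.0541 to 0.0842), and Fcgr1 without Con 3 (adjusted p = 0.0536). Of 4 cholangiocyte markers 2 rose, Spp1 among them, and among 6 red cell markers Bpgm rose and Alas2 fell. Pnpla2 and Cidea rose among 3 adipocyte markers. Of 13 hepatocyte secreted proteins, Trf and Ambp rose and 5 fell, namely Apoc3 (10087 ± 914 to 3435 ± 745 TPM), Apoa2, Apob, Ttr and Serpina1c. Of 9 pericentral genes, 4 fell, among them Lect2 (308 ± 51.4 to 52.9 ± 28.9 TPM), Cyp1a2 and Tbx3, and Cyp2e1 and Glul rose. Of 11 periportal genes, Etnppl, Hal, Cyp2f2, Gls2 and Aldh1b1 fell and Hsd17b13 rose, and 6 genes of each list were lower in libraries 26 to 29. Of lists with fewer than 3 measured members, the platelet markers Pf4 (log2 change 2.82 ± 0.21) and Itga2b (-0.39 ± 0.15) passed in opposite directions. Cela1, an elastase and the 1 measured marker of exocrine pancreas, fell from 25.5 ± 8.05 to 12.0 ± 2.13 TPM. Ighm, the 1 measured B cell marker, did not pass (3.69 ± 1.17 and 2.80 ± 0.769 TPM). All 13 T and NK cell markers are in the data, but none had a mean of at least 1 TPM.

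Scores per liver are taken relative to the median of all genes, which rose in SAP, so a lower score need not be a fall of the members: mean log2 changes were -0.14 for coagulation (median 0.01) and -0.19 for hepatocyte secreted genes (median -0.05), against score differences of -0.42 and -0.46. Scores, which were compared between livers and not between genes, differed between SAP and controls in several of the lists that camera did not call. They were lower in SAP for coagulation and complement (difference -0.42, exact permutation adjusted p = 0.00131), heat-shock (-0.57, 0.000676), female-biased (-0.71, 0.000908), urea cycle (-0.57, 0.0328), endothelial (-0.63, 0.00115), stellate cell (-0.57, 0.000908), hepatocyte secreted (-0.46, 0.00509), pericentral (-0.67, 0.0066) and periportal genes (-0.82, 0.00175). They were higher for glucocorticoid-responsive (0.84, 0.000359), extracellular matrix (0.48, 0.0024), cell cycle (0.28, 0.0256) and adipocyte genes (1.39, 0.000359). They did not pass for interferon-stimulated (0.457), gluconeogenesis (0.414), clock (0.961), ribosomal (0.194), monocyte (0.105), cholangiocyte (0.819) and red cell genes (0.284). Without SAP 21 to 25 camera also called the urea cycle, coagulation, Kupffer cell, hepatocyte secreted, pericentral and periportal lists as lower (adjusted p = 0.00228, 0.0155, 0.0299, 0.025, 0.0201 and 0.0155), and with no filter the endothelial list (0.0234).

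**Figure D3:**
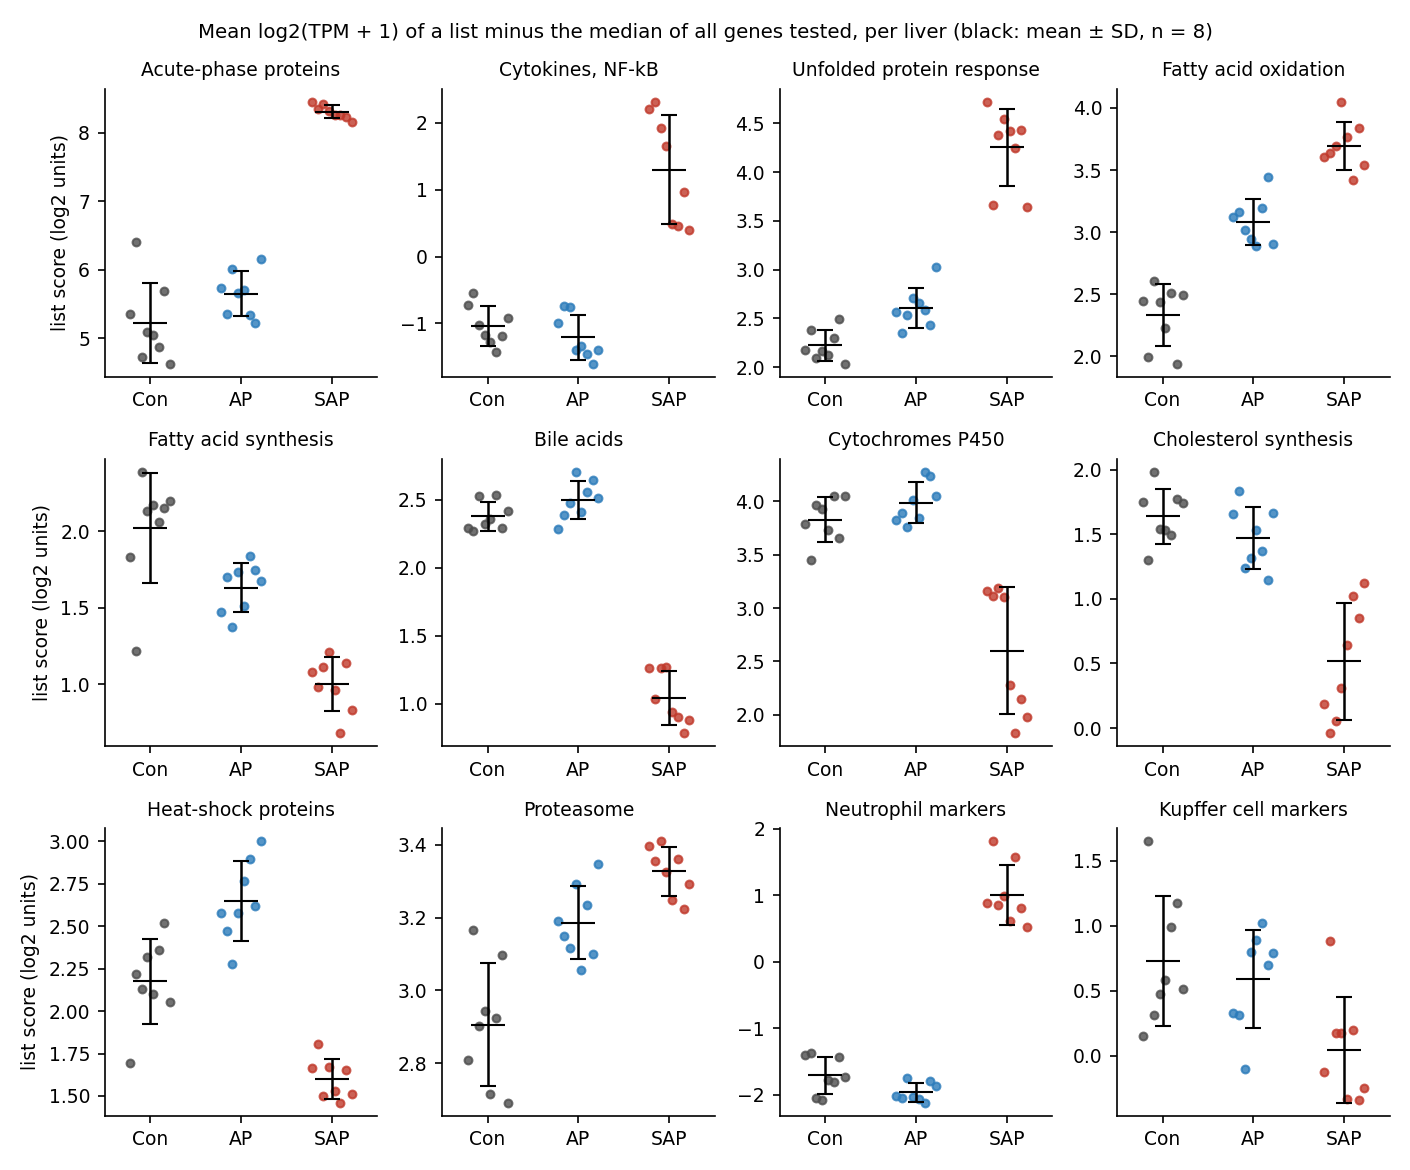
Scores of 12 gene lists in single livers: mean log2(TPM + 1) of the members minus the median of all tested genes (vertical axis), by group (horizontal axis). Points are livers, and bars show the mean ± SD (n = 8 per group), such as 8.31 ± 0.10 in SAP and 5.22 ± 0.59 in controls for acute-phase genes.

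Among the genes named for SAP, levels of Hsd3b5, Cyp2c40, Acat2, Klkb1, Cyp2b13, Pcna, Rpl28, Rps15, Rpl14 and Ndufb4c are uncertain because at least 20% of their 50-base windows occur in other genes. Gclm, Klkb1 and Spp1 overlap another gene on their own strand. Whether the libraries kept the strand is not given in the sources used here, so levels of Cebpd, Fdft1, Nr1i3, Acss2, Dbp, Alas2, Psmd13, Abcb11, Selp, Irak3, Fgg, Keg1, Gbp2, Cdkn1a, Elovl6, F13a1, Col4a1 and Col4a2 also carry the uncertainty of a gene on the opposite strand.

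The comparison of SAP with AP livers asked which transcripts separate the severe from the other disease group. In SAP 23 of 23 cytokine, chemokine and NF-kB feedback genes were higher, and 16 of 25 bile acid genes and 18 of 25 cytochrome P450 genes were lower, while 4 and 3 were higher. Camera called these lists too only with the preset correlation. Cd14 was 326-fold higher in SAP than in AP (1.45 ± 0.483 TPM in AP, adjusted p = 7.2e-17), and Ier3 75.9-fold higher (adjusted p = 1.29e-19). Hsd3b1, a steroid dehydrogenase, fell by 5.86 ± 0.13 on the log2 scale from 66.3 ± 13.1 TPM in AP to 0.149 ± 0.170 TPM in SAP (adjusted p = 3.31e-21).

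Between SAP and AP, 7607 of 10555 genes passed (72.1%), 4332 higher and 3275 lower in SAP, and 3613 differed by at least 1 on the log2 scale (2020 up, 1593 down). The median log2 change of all genes was 0.13. Centring each library on its median, which moves all its genes alike, gave 3708 up and 4278 down with a median of -0.10. The other large rises were those of Igfbp1 (log2 change 8.09 ± 0.39), Saa3 (7.71 ± 0.65) and Il1rn (6.69 ± 0.24). The other large falls were those of Ccdc152 (fell by 6.37 ± 0.28), Keg1, an acyltransferase family gene (fell by 5.95 ± 0.18), Hsd3b5 (fell by 5.90 ± 0.17) and Angptl8 (fell by 5.87 ± 0.27). Of the 122 named genes, chosen by their values, 115 passed, 100 of them with no overlap between groups. Among all 10555 genes tested 3932 did not overlap. Derl3 did not pass (adjusted p = 0.191) except without SAP 22 (adjusted p = 0.00103). Fcgr1 passed without AP 18 or SAP 22 (0.0146 and 0.00766) and Ighm without AP 13, AP 19, SAP 26 or SAP 28 (0.0205 to 0.0499).

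Of the 37 lists, 16 passed between SAP and AP, 7 upward and 9 downward, and 0 with an estimated correlation. Higher lists were the acute-phase genes, 27 of 29 (camera adjusted p = 4.23e-07, adjusted p = 0.535 with an estimated correlation), cytokines and chemokines, 23 of 23 (camera adjusted p = 4.79e-07, adjusted p = 0.535 with an estimated correlation), and immediate-early genes, 14 of 14 (camera adjusted p = 1.83e-05, adjusted p = 0.535 with an estimated correlation). STAT3 signalling genes rose in 12 of 14 (camera adjusted p = 0.000294, adjusted p = 0.535 with an estimated correlation), neutrophil markers in 6 of 6 (camera adjusted p = 0.000294, adjusted p = 0.498 with an estimated correlation) and p53 targets in 13 of 14 (camera adjusted p = 0.00517, adjusted p = 0.535 with an estimated correlation). The unfolded protein response rose in 20 of 22 genes and fell in Atf5 (camera adjusted p = 4.66e-05, adjusted p = 0.614 with an estimated correlation), with Hspa5 going from 94.9 ± 42.8 TPM in AP to 1595 ± 590.0 in SAP. Adjusted over the list alone the counts were equal, apart from 1 p53 target, Bbc3, that fell. Here too, genes near 0 outside SAP could pass the filter on mean TPM only through SAP.

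Lower lists included the cytochromes P450, where 18 of 25 genes fell and Cyp2b10, Cyp3a11 and Cyp3a13 rose (camera adjusted p = 0.000149, adjusted p = 0.535 with an estimated correlation), and bile acid genes, where 16 fell (17 adjusted over the list alone) and Cyp2c70, Baat, Acox2 and Abcc3 rose (camera adjusted p = 0.00034, adjusted p = 0.498 with an estimated correlation). Abcb11 went from 115 ± 16.2 TPM in AP to 4.48 ± 2.03 in SAP. Heat-shock genes fell in 9 of 13 and rose in Hspd1 and Bag3 (camera adjusted p = 0.0157, adjusted p = 0.657 with an estimated correlation), with Hspa1b going from 13.6 ± 3.95 to 0.724 ± 0.467 TPM, and cholesterol synthesis genes fell in 17 of 24 and rose in Srebf2 and Hsd17b7 (camera adjusted p = 0.00986, adjusted p = 0.726 with an estimated correlation). Growth hormone axis genes fell in 9 of 13 and rose in Egfr (camera adjusted p = 0.0139, adjusted p = 0.646 with an estimated correlation), Igf1 going from 966 ± 134 to 472 ± 90.0 TPM. Coagulation and complement genes fell in 14 of 31 and rose in 6 (camera adjusted p = 0.0142, adjusted p = 0.682 with an estimated correlation), and pericentral genes fell in 5 of 9 (Cyp1a2, Slc1a2, Lect2 and Tbx3 among them) and rose in Glul (camera adjusted p = 0.0413, adjusted p = 0.657 with an estimated correlation). Respiratory chain genes fell in 47 of 82 and rose in 12 (camera adjusted p = 6.22e-06, adjusted p = 0.646 with an estimated correlation), and ribosomal protein genes fell in 37 of 76 and rose in 14 (camera adjusted p = 0.00883, adjusted p = 0.777 with an estimated correlation). The exact permutation adjusted p of the score per liver was 0.000303 for each of these 16 lists except the ribosomal one (0.00275). Without SAP 26 to 29 the calls of heat-shock, coagulation, growth hormone and pericentral genes ended (adjusted p = 0.0737, 0.148, 0.204 and 0.32), as did those of cholesterol and ribosomal genes without SAP 21 to 25 (0.095 and 0.154). Quantile normalization ended the coagulation, growth hormone, ribosomal and pericentral calls (0.199, 0.0728, 0.635 and 0.126), and removing length and GC trends the ribosomal call (0.39).

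The other lists did not pass between SAP and AP in the main test. Other settings called the fatty acid oxidation list as higher (quantile normalization 0.0373, no filter 0.0224) and the proteasome list as higher (quantile normalization 0.00799). They called as lower the fatty acid synthesis list (no filter 0.0129, rescaling 0.0403, without SAP 21 to 25 0.0454, length and GC trends removed 0.0347), the NRF2 list (rescaling 0.00881, without SAP 21 to 25 0.0186), the endothelial list (no filter 0.013, rescaling 0.0459), the hepatocyte secreted list (no filter 0.00859, without SAP 21 to 25 0.00593), and without SAP 21 to 25 the urea cycle (0.00442) and periportal lists (0.0474). Fatty acid oxidation genes rose in 17 of 25 and fell in 5, Cpt2, Acadvl, Acaa2 and Ech1 among them (camera adjusted p = 0.135, exact permutation adjusted p = 0.000575), with Plin2 at 111 ± 22.3 TPM in AP and 1056 ± 284 in SAP, and fatty acid synthesis genes fell in 10 of 20 and rose in Fasn, Scd1, Me1 and Lpin1 (camera adjusted p = 0.0621). Interferon-stimulated genes rose in 6 and fell in 5 of 26 (6 and 4 adjusted over the list alone), with a median of -0.18 and a mean of 0.30. Proteasome genes rose in 19 of 37 and fell in 7 (18 and 7 adjusted over the list alone). Kupffer cell markers fell in 6 of 11 and rose in Marco, and endothelial markers fell in 7 of 10 and rose in Stab2 and Lyve1. Median and test also differed in sign from the mean for gluconeogenesis genes, and the median from mean and test for extracellular matrix genes. By score per liver, again relative to a median that was higher in SAP, SAP was lower than AP for fatty acid synthesis (difference -0.63, exact permutation adjusted p = 0.000303), NRF2 target (-0.45, 0.00235), female-biased (-1.02, 0.000303), Kupffer cell (-0.54, 0.022), endothelial (-0.58, 0.00383), hepatocyte secreted (-0.61, 0.000303) and periportal genes (-0.66, 0.0193), and higher for glucocorticoid-responsive (0.99, 0.000303), extracellular matrix (0.50, 0.00442), cell cycle (0.34, 0.00391), proteasome (0.14, 0.00958) and adipocyte genes (1.26, 0.00164).

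Both disease groups were compared with the same controls, so their changes share chance values. Of the genes that passed in both, 295 rose in both and 104 fell in both, while 82 rose in AP and fell in SAP and 6 did the opposite. Lists of these sizes drawn independently share 202.7 rises and 35.5 falls. Fold changes of AP and SAP correlated across genes, which are not independent replicates, with r = 0.344, against 0.505 in simulations of unchanged groups. Their covariance was 0.158, against a simulated mean of 0.0288 and highest value of 0.0596, a difference of 0.129 with a jackknife standard error of 0.0514 over libraries for the covariance. Other splits of the same libraries into groups of these sizes gave covariances of up to 0.350, and 12 of 100, the real one included, gave one as large, so this test does not separate it from chance. Those splits mix SAP livers with the others, so their covariances are not those of unchanged groups. With the controls split into sets of 4, 1 for each comparison, the covariance had a median of 0.131 over 70 splits (0.0808 to 0.170), and a median of 31.5 genes rose (8 to 740) and 16 fell in both (1 to 143). Cyp4a14 (log2 change 3.11 ± 0.40 in AP and 4.32 ± 0.40 in SAP), Plin2 and Derl3 rose in both, Elovl6 and Gstm3 fell in both, and Hspa1b rose in AP and fell in SAP. The number changed the same way, 399, fell to 149, 122, 158, 123, 149, 239 or 158 without Con 1, Con 7, Con 10, AP 15, AP 17, AP 18 or AP 19 respectively.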

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

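The tests of the divide within SAP by title number, the test of 1 batch across groups, the tests of a few abundant genes on the share of rises and on the 3 complexes in AP, and all tests of the mitochondrial share were chosen after the result was seen. A Dixon-type test marked 25 of 375 groups of 8 livers (6.67%) in which 1 library lay far from the others, and chance marks about 1 in 20 groups.

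In controls, Con 3 lay above the others for Cd14 (15.16 TPM, others 0.47 to 1.29), Il1rn (4.54, others 0.06 to 0.87), Ccl5 (29.17, others 1.29 to 3.78), Klf6 (1.46, others 0.52 to 0.88) and Marco (22.24, others 0.2 to 1.81). Con 6 was high for Hspa1b (15.23, others 3.35 to 6.97) and Pdk2 (43.82, others 30.75 to 36.38), Con 9 for Ngp (0.18, others 0 to 0.08) and Con 10 for Egr1 (1.36, others 0.13 to 0.46). Con 7 was low for Mcm3 (1.16, others 2.51 to 3.65), Con 8 for Apol11b (327.34, others 536.66 to 792.35), and Con 10 listed n-R5s146 at 0 (others 28.03 to 322.83).

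In AP, AP 18 was low for Apol11b (50.54 TPM, others 237.7 to 746.4), Gadd45g (6.39, others 15.38 to 28.26) and Errfi1 (21.03, others 53.27 to 83.82), and its major urinary protein genes took 18.833% of TPM (others 12.781 to 15.374%). AP 12 was high for Igf1 (1258.14, others 815.08 to 995.83), AP 11 for Ighm (12.12, others 1.95 to 4.8) and AP 17 for Cidea (0.18, others 0 to 0.08), and AP 13 was low for Dnase1l3 (12.6, others 20.46 to 29.53). In SAP, SAP 22 was low for Derl3 (4.77, others 32.43 to 94.69) and high for Ccl5 (334.19, others 121.22 to 177.83), Cebpd (37.79, others 16.26 to 21.65) and Dnase1l3 (9.27, others 5.11 to 6.44), and SAP 28 was high for Cidea (12.76, others 1.11 to 4.13).

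Other splits of the same libraries into groups of the same sizes were drawn 100 times, the real one included, for each comparison. For the numbers of genes, the real split called the most in each comparison. AP against controls called 578 (1 of 100 as large, highest other 4), SAP against controls 7808 (1, highest other 6412) and SAP against AP 7607 (1, highest other 3829). This argues against a chance division, to the limit of 1 in 100, if the libraries are independent, which the labels do not state. The 399 genes changed the same way in both (1, highest other 0) are not tested this way, since the 24 libraries were relabelled for it and the other relabellings called 0 genes for AP, which left none to share. Chance cannot be excluded for the numbers of lists, which were 13, 15 and 16 against highest others of 19, 23 and 25 (33, 42 and 28 of 100 splits as large). The covariance of fold changes (0.158, highest other 0.350, 12 of 100) is not decided by this test. Its relabelled groups mix SAP with other livers, so they are not unchanged groups, for which simulations gave at most 0.0596.

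The first pattern weighed is the divide within SAP, where 3708 genes differed between libraries 21 to 25 and 26 to 29. Of the 35 splits of the 8 libraries into sets of 4, 1 gave as many genes and the highest other gave 4, but the division was chosen because these libraries stood apart, so this rank does not test chance. A trend on gene length or GC content is argued against, as 94.5% of these genes (3505) still passed with it removed, and so is 1 batch that follows the numbers in all groups, as late minus early differences in SAP correlated across genes at 0.0705 with those in controls and 0.139 with those in AP. A batch, day or cage within SAP, or 2 courses of the disease, may have produced the divide, and the labels name none of these.

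The second pattern is the excess of rises in AP, 79.4% of the genes that passed. Removal of a trend on gene length or GC content left 77.1%. Each library kept its mean in that step, so a shift of all genes alike stayed, and this share does not decide. For the respiratory chain, ribosomal and proteasome lists such a trend is argued against, as 3 of 3 stayed called. A few abundant genes holding less of the total stay open for both: rescaling without the 50 most abundant genes gave 47.4% and 3 of 3 lists, but it lowers nearly all genes alike, so any cause of such a shift would lower the share, and it also changed which genes were tested and ended 3 other list calls, so the 3 lists do not decide it. The list calls are themselves uncertain, since none held with an estimated correlation (camera adjusted p = 0.683, 0.731 and 0.731), the scores per liver missed for the respiratory chain and ribosomal lists (exact permutation adjusted p = 0.123 and 0.0805, proteasome 0.0115), and quantile normalization ended the respiratory call (0.0953). A response to pancreatitis and RNA quality were not tested.

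The third pattern is the fall of the mitochondrial share of TPM (log2 change of the share -1.94 in SAP and -0.65 in AP). Displacement by a few risen nuclear genes is argued against, as the nuclear genes tested moved by a median of 0.214 in SAP and 0.0621 in AP. Reads moved to nuclear copies of mitochondrial DNA are argued against too, as mitochondrial genes and 7 such copies together took 28.4 ± 6.02% in controls, 18.0 ± 3.44% in AP and 7.38 ± 1.65% in SAP. Less mitochondrial RNA in these livers, or a difference in RNA quality or selection between groups, may account for it, and none of these was tested.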

How the results depend on the processing

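The settings that leave out Con 3 and 9, SAP 21 to 25 or SAP 26 to 29, the rescaling, the covariate for title numbers, the removal of length and GC trends and the list scores were chosen after the results were seen. No paired analysis was possible because the groups share no replicate numbers. For AP against controls (578 genes), centring gave 1006 genes, array weights 1458, no filter 222, a log2 change of at least 1 84, an adjusted p under 0.01 78, and leaving out Con 3 and 9 911. Leaving out 1 library gave 180 to 841 genes, with 210 without Con 1, 180 without Con 7, 226 without Con 10, 181 without AP 15, 211 without AP 17, 340 without AP 18 and 237 without AP 19. Between 409 and 848 genes passed under the other settings run. The fold threshold lowered SAP against controls from 7808 to 4031 and SAP against AP from 7607 to 3613, and leaving out 1 library gave 7669 to 7831 and 7431 to 7640. With an estimated correlation camera called 0, 0 and 0 lists (1, 2 and 2 at an unadjusted p under 0.05). The list scores called 6, 30 and 29 lists in place of 13, 15 and 16, and without SAP 21 to 25 the lists of SAP against controls became 23. Leaving out 1 library gave 11 to 16, 14 to 16 and 15 to 18 lists. The covariance became 0.0693 with no filter, which adds genes of low level, and ranged from 0.139 to 0.186 without 1 library. Genes changed the same way in both (399) became 151 with no filter and 45 with split controls, and 122 to 585 without 1 library (149 without Con 1, 122 without Con 7, 158 without Con 10, 123 without AP 15, 149 without AP 17, 239 without AP 18 and 158 without AP 19). The total per library, 991249 on average, was 438414 without the 50 most abundant genes. Over the named genes and comparisons, leaving out 1 library kept 8676 results, made 26 pass and 82 miss, and turned none. Quantile normalization kept 358 of 366, no filter 356 and the 2 groups alone 357, and a fit without trend kept all 366. Apart from the construction of settings with fewer libraries, stricter thresholds or more genes, the cause was not tested. Depth is unknown, so no limit from depth can be given.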

Other observations

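The tests in this part, with 12 further gene lists written once the report's results were known and before the lists' own values were seen, were all chosen after the main results, and the genes named here were chosen after their values were seen. List scores per liver were compared by exact permutation tests, two-sided, adjusted over 12 lists.

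Autophagy and lysosome genes rose in 13 of 17 members between SAP and control livers and fell in 3 (score 0.47 higher, adjusted p = 0.000311, all 8 SAP livers above every control). Ctsl, a lysosomal protease, rose from 77.3 ± 31.8 to 1523 ± 276 TPM, Lamp1, a lysosomal membrane protein, from 55.7 ± 16.9 to 163 ± 25.5 TPM, and Wipi1 from 2.55 ± 0.638 to 17.0 ± 2.20 TPM. Tfeb, the transcription factor of lysosomal genes, fell from 8.04 ± 1.56 to 1.07 ± 0.601 TPM and Atg7 from 26.7 ± 3.75 to 5.99 ± 1.35 TPM. Glycolysis and hypoxia genes rose in 8 of 14 and fell in 4 (score 0.64 higher, exact permutation adjusted p = 0.000311, all 8 SAP livers above every control). Ldha, lactate dehydrogenase, was at 101 ± 36.7 TPM in controls, 245 ± 73.9 in AP and 2953 ± 369.8 in SAP, and Pfkfb3, an activator of glycolysis, went from 1.18 ± 0.470 to 21.8 ± 4.88 TPM, while Vegfa fell from 18.7 ± 5.96 to 7.46 ± 2.16 TPM. Tubulin and actin genes rose in 7 of 10 and fell in 1 (score 1.03 higher, adjusted p = 0.000311, again without overlap), Tubb6 from 2.82 ± 1.05 to 46.6 ± 12.4 TPM and Actg1 from 19.9 ± 10.9 to 163 ± 89.6 TPM. Anti-inflammatory and nitric oxide genes rose in 5 of 8 and fell in 1 (score 0.57 higher, adjusted p = 0.000799, 6 of 8 SAP livers above every control), with Il10 at 0.166 ± 0.155 and 4.92 ± 3.33 TPM.

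Genes of iron handling moved apart in SAP, 8 of 14 up and 6 down (score difference -0.33, adjusted p = 0.000311, all 8 SAP livers below every control, though the median log2 change of the members was 0.57, of the opposite sign, as the score is a mean taken relative to the median of all genes). The importers Slc39a14 and Slc11a2 rose from 12.4 ± 4.43 to 97.8 ± 35.0 TPM and from 2.58 ± 0.816 to 16.0 ± 3.49 TPM, and the exporter Slc40a1 fell from 9.20 ± 3.80 to 0.802 ± 0.713 TPM. Of the ferritin chains, Fth1 was at 1175 ± 356 and 3239.9 ± 372 TPM and Ftl1 at 7719 ± 1078 and 2924 ± 589 TPM. Shared sequence was not examined for genes named only here. Conjugating enzymes fell in 17 of 30 and rose in 6 (score difference -1.01, adjusted p = 0.000311, all 8 SAP livers below every control). Apolipoprotein genes rose in 3 of 15 in AP (score 0.26 higher, adjusted p = 0.00124) and rose in 4 and fell in 6 in SAP (score difference -0.28, adjusted p = 0.00642), Apoa4 from 244 ± 94.9 to 1175 ± 367 TPM in AP (limma adjusted p = 2.37e-05) and to 2095 ± 722 TPM in SAP. Histone genes rose in 6 and fell in 11 of 18 in SAP (score difference -0.43, adjusted p = 0.00326), hepatocyte transcription factors rose in 5 and fell in 4 of 16 (score difference -0.41, adjusted p = 0.000311, median log2 change of members -0.03), and peroxisome genes (8 up, 4 down of 16, adjusted p = 0.651), aminoacyl-tRNA synthetases (19 up, 8 down of 34, 0.0565) and major urinary protein genes (4 up, 8 down of 20, 0.201) did not pass. In AP against controls, scores were higher by 0.19 for autophagy and lysosome (adjusted p = 0.00124), 0.27 for histones (0.00124), 0.23 for peroxisome (0.00187), 0.11 for aminoacyl-tRNA synthetase (0.00895), 0.18 for glycolysis and hypoxia (0.0458) and 0.39 for tubulin and actin genes (0.0458). The lists of iron handling, conjugating enzymes, hepatocyte transcription factors, major urinary proteins and anti-inflammatory genes did not pass there (0.751, 0.466, 0.162, 0.142 and 0.776). The summed share of TPM of the major urinary protein genes, which weighs the most abundant members most, was nevertheless higher than in controls (10.0 ± 2.73%) both in AP (14.4 ± 2.05%, exact permutation adjusted p = 0.00787 over 24 tests of library measures) and in SAP (13.8 ± 3.06%, exact permutation adjusted p = 0.0423).

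Interferon-stimulated genes differed within SAP by title number. Mx1, an antiviral GTPase, averaged 65.1 TPM in libraries 21 to 25 and 1.92 in 26 to 29, Ifit3 67.8 and 9.94 TPM, and Cxcl10, a chemokine, 62.4 and 6.78 TPM, while Cxcl9 averaged 488 and 419 TPM (limma adjusted p = 0.38). The score of the list was between 2.50 and 2.61 in libraries 21 to 25 and between 0.85 and 1.17 in 26 to 29. Across controls it lay between 0.92 and 2.83, and across AP livers between -0.54 and 2.75.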
